A study of Mus musculus with 4 samples.

How the data were processed

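RNA of the mouse suprachiasmatic nucleus (SCN), the hypothalamic nucleus that holds the master circadian clock, was measured on 4 Affymetrix arrays. The arrays form a design of 2 surgical states by 2 times, with 1 array in each of the 4 groups. HPX mice had been hypophysectomized, that is, their pituitary gland had been removed, and the control mice are called non-HPX. The times were Zeitgeber time (ZT) 2, early in the light phase, and ZT14, early in the dark phase, of a cycle of 12 h light and 12 h dark. Per the series design text, the tissue was cut out by laser microdissection and that of 10 animals per time point was pooled; whether this means 10 animals in each surgical state is not stated. Per the labels' protocols, biotin-labelled cDNA was made with the WT PLUS kit and 5.5 µg of fragmented cDNA was used. Each value therefore stands for a pool on 1 array, and the spread between animals was not measured.

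The deposited table holds log2 expression values that the authors made with robust multi-array averaging (RMA) in Affymetrix Expression Console, per the submitters' processing notes; the versions are not given in the sources used here. RMA subtracts a background estimate, forces all arrays onto 1 intensity distribution and summarises the probes of each probeset, so a change shared by most genes cannot be seen in these values. The table has 41345 probesets with no missing values. The median over probesets lay between 5.448 and 5.516 on the 4 arrays and the SD between 2.027 and 2.064, both extremes of the SD being ZT2 arrays (HPX the narrowest, non-HPX the widest). Array number, not read depth, limits the precision here.

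Gene names came from the platform annotation. Of the 41345 probesets, 23521 named exactly 1 gene, 1814 named several and 16010 were not listed there and stayed unnamed. Symbols were looked up by Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, which held 23328 of the 23521 and changed 0 symbols; the build behind the array annotation is not named, so no coordinates are printed. The mean of the single-gene probesets was taken per gene, which gave 22180 genes, 21098 of them with 1 probeset and 1082 with several. A gene counted as expressed when the highest of its 4 values reached the median of all genes' highest values, a floor of 6.02, which kept 11090 genes.

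With 1 array per group, the comparisons between pairs of groups are log2 differences without a replicate check and without a p-value. Expressed genes at least 1.5-fold apart were counted in each direction (2-fold for the difference of the night change between states). The night changes of the surgical states share no array, nor do the HPX effects at the 2 times, so genes that moved the same way in both were counted and set beside the number that independent lists would share. An additive model of time and surgery was fitted to all 4 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom, and that residual is the interaction of time and surgery, so a real interaction counts as noise. In eBayes this residual is weighed with 8.772 prior degrees of freedom estimated over all genes. The adjusted p-values therefore rest mostly on a spread shared by all genes. A gene's own spread between pooled samples across the other factor counts for little. Standard errors (SE) beside log2 changes come from this fit. In 5 simulated runs for the time effect over 11090 genes, 200 of them changed, limma recovered 69.2% of changes of 0.6 on the log2 scale and 100% of changes of 1, 1.5 and 2, while 11.51% of its calls were false. The same 5 runs gave 3 surgery calls where no surgery effect was simulated. The noise was drawn independently for each gene and array from the prior that limma had fitted, with no interaction. The model's assumptions thus held in the runs, and these rates need not hold for the real arrays.

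For 24 gene lists, fixed together with the comparisons, alternatives and naming rule before the data were examined, the median log2 difference of the expressed members was given a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list needed at least 3 expressed members. The percentile describes these arrays and is not a p-value, since genes that are regulated together do not behave as random draws. Tested on simulated data for the night change in non-HPX over 11090 genes, lists of 15 genes shifted by 0.3 lay above the 97.5 percentile in 20 of 20 runs, and 0 lists without a shift lay outside the bounds of 2.5 and 97.5. These simulated rates need not hold for the real arrays, where 36 of 100 combinations of a list and a difference lay outside the bounds. Counts of list members in the additive fit are given over all genes and adjusted over the list alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for all steps other than the limma fits.

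The named genes followed a rule. For time of day, the 10 genes with the highest and the 10 with the lowest mean night change were named among genes at least 1.5-fold apart the same way in both states, leaving out predicted and non-coding names and the olfactory and vomeronasal receptors; the same rule was used for surgery, and the 5 highest and 5 lowest values for the difference of differences. Members of the core clock, neuropeptide and pituitary hormone lists could be named whatever their value, members of other lists when at least 1.5-fold apart in any pairwise difference or, for cell types, when among the 4 most abundant. Genes outside the rule were chosen after their values were seen: Gm7361, Mfsd2a, Cirbp, Fkbp5, Tagln, Snord66 and Snord1b, and, for passing adjusted over the list alone, Gpr176, Six6, Fos, Egr1, Sgk1, Hr, Hspa5, Opalin and Abcb1a. The alternatives were no expression filter, a filter at the 70th percentile, centring of each array on its median, cyclic loess between arrays, the probeset with the highest mean in place of the average, a 2-fold threshold (3-fold for the difference of differences), an intensity trend or robust fitting in limma, 10 expression bins, and list means in place of medians.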

Results

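Gene expression in the SCN was profiled in hypophysectomized and control mice at ZT2 and ZT14 to compare day and night expression with and without the pituitary. There were 4 groups of 1 array each, every array made from pooled laser-microdissected tissue, so no value below has replicates within its group. Of 22180 genes, 11090 were expressed. Across these genes the arrays of the same time resembled each other more than arrays of the same surgical state: Pearson's r was 0.9866 between the ZT2 arrays and 0.9883 between the ZT14 arrays, against 0.9855 between times in non-HPX and 0.9789 in HPX. Arrays that shared neither time nor state stood at 0.9823 (non-HPX ZT2 with HPX ZT14) and 0.9819 (non-HPX ZT14 with HPX ZT2). Both were above the value between the HPX arrays. These correlations are across genes, which are not independent replicates.

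Night was compared with day in each surgical state. Prok2 (probeset 17469455), which encodes the SCN output peptide prokineticin 2, fell furthest, from 9.17 at ZT2 to 5.45 at ZT14 in non-HPX and from 9.08 to 5.61 in HPX (log2 values), 13.2-fold and 11.1-fold. Both ZT14 values of Prok2 lay below the floor of 6.02, so the size of its folds is uncertain. Rasl11b, a Ras-like protein, fell 9.27-fold and 6.89-fold. Rasd1 (probeset 17263511), a small G protein known for its induction by glucocorticoids, rose most, 4.45-fold in non-HPX and 10.2-fold in HPX. The activity-dependent transcription factor Npas4 rose 1.89-fold and 3.38-fold, and Npbwr1, a receptor for neuropeptides B and W, 1.96-fold and 3.29-fold. The ZT2 values of both genes lay below the floor in both states, as did Npas4 at ZT14 in non-HPX (5.97), so these folds are uncertain too. Also higher at night in both states were Sertm1, the guidance molecule Sema3e, Tafa4, Hs3st1, the vasopressin receptor Avpr1a, Csta2 and the chaperone Dnajb1, with mean changes from 0.88 (Dnajb1) to 1.34 (Sertm1). Lower at night were the MAP kinase phosphatases Dusp4 and Dusp1, the kinase Sik1, the clock repressor Nr1d1, Fosl2, Rgs16, the brain fatty acid-binding protein Fabp7 and Zfp972, with mean changes from -1.08 (Zfp972) to -1.69 (Dusp4). Among these genes, Dusp4 at ZT14 (5.86 in non-HPX and 5.74 in HPX) lay below the floor. Sertm1 (5.59 and 5.62) and Hs3st1 (5.42 and 5.45) did so at ZT2. Csta2 and Zfp972 belong to families of close copies, and which copy was measured is uncertain.

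In the additive limma fit all 20 of these genes passed an adjusted p of 0.05, among them Prok2 at -3.60 ± 0.12 (SE; adjusted p = 5.84e-07), Rasl11b with a mean fold of 7.99 (adjusted p = 4.47e-06) and Rasd1 at 2.75 ± 0.22 (adjusted p = 0.000739). They had been picked for a large mean change shared by both states, which is what the fit measures, so their passing is no separate test. In all, 60 genes passed, 22 higher and 38 lower at night. The count was 1 without the expression filter and 244 after cyclic loess, which kept all 60. At least 1.5-fold the same way in both states were 22 genes higher and 34 lower at night, against 0.43 and 0.67 for independent lists, and 0 genes moved that far in opposite ways (1.14 for independent lists). Across all expressed genes the night changes of the states were less alike, with Pearson's r of 0.308 and Spearman's rho of 0.149.

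**Figure D1:**
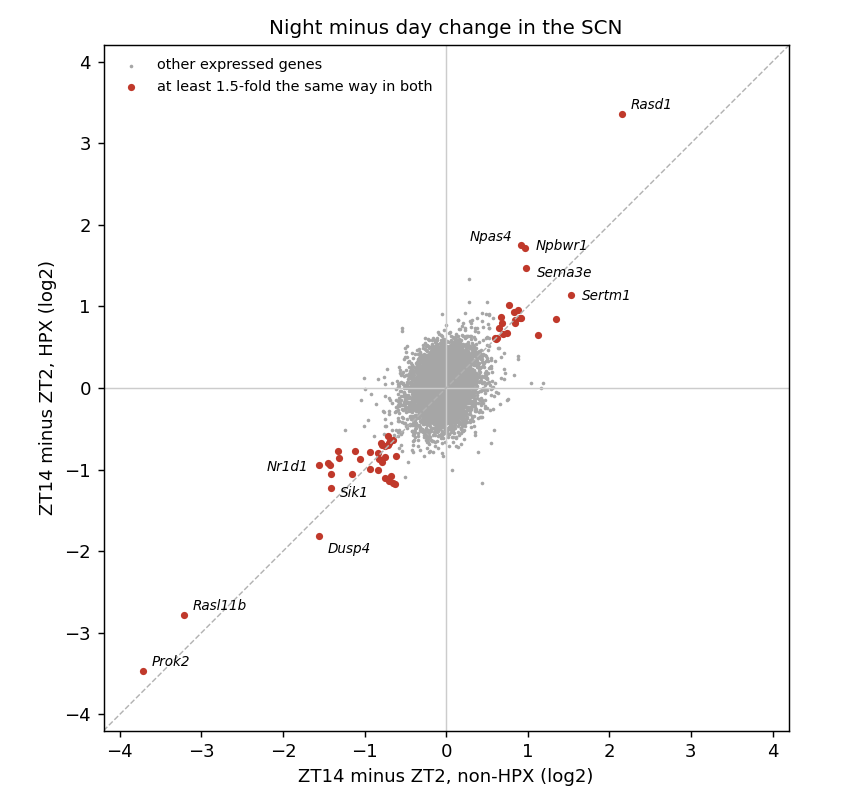
Each point is an expressed gene, with its ZT14 minus ZT2 difference (log2) in non-HPX on the horizontal axis and in HPX on the vertical axis; the dashed line marks equal change and there is 1 array per group. The 56 genes at least 1.5-fold apart the same way in both states are red; Prok2 (-3.72 and -3.47) and Rasl11b (-3.21 and -2.78) lie farthest out among those lower at night and Rasd1 (2.15 and 3.35) among those higher.

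Of the 24 core clock genes, 20 were measured by a probeset of their own and all 20 were expressed; Per2 and Csnk1d were among those not analysed here. Over all genes 2 rose and 5 fell at night, and 3 rose and 7 fell when adjusted over the list alone. The period gene Per1 fell by 1.06 in non-HPX and by 0.87 in HPX (log2; adjusted p = 0.00739), and its partner Cry1 rose by 0.85 and 0.80 (adjusted p = 0.00944). Arntl, which encodes the activator BMAL1, rose by 0.52 and 0.91 (adjusted p = 0.0444). Nr1d1, Bhlhe41, the output factor Dbp and Ciart fell, Nr1d1 by 1.55 and 0.95, Bhlhe41 by 0.82 and 0.86 and Dbp by 0.74 and 0.71. Adjusted over the list alone, Npas2 also rose and Nr1d2 and Rorb also fell. The others did not pass, with Per3 at 0.05 and 0.06 and Clock at 0.22 and 0.15. Tef rests on probesets that disagreed, -0.07 and -0.51 in non-HPX. The list's median was -0.23 in non-HPX (percentile 0.0 among random lists) and -0.00 in HPX (percentile 11.76), where its sign changed with the scaling; the list mean in HPX lay at percentile 0.49. By limma 0 of the 20 clock genes passed for surgery, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05; their medians for HPX minus non-HPX were -0.10 at ZT2 (percentile 20.7) and 0.09 at ZT14 (percentile 96.54).

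Of 20 SCN neuropeptides and receptors, 14 were expressed. For time of day, Prok2 fell and Avpr1a rose over all genes, and adjusted over the list alone the VIP receptor Vipr2 rose too, by 0.50 and 0.36. The peptides of the main SCN cell classes did not pass: Vip differed by 0.25 in non-HPX and 0.03 in HPX, Grp by 0.00 and -0.25, Nms by -0.22 and -0.38, and Avp by 0.04 and 0.67. The list medians for night were 0.05 (percentile 95.36) and 0.07 (percentile 60.17), while the list mean, pulled by Prok2, lay at percentiles 0.24 and 0.65. Avpr1b, Pdyn, Tac1, Nts, Nmu and Nmur2 were below the floor. Among 11 SCN identity genes, all expressed, Rasd1 rose and Rgs16 fell, and adjusted over the list alone 3 rose (Rasd1, Vipr2, Gpr176) and 3 fell (Rgs16, Rorb, Six6). Their medians for night were 0.01 (percentile 72.14) and 0.11 (percentile 80.15). Rorb and Vipr2 each stand in a further list.

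Immediate early genes were mostly lower at night. Of 12 expressed members, Fosl2, Dusp1 and Nr4a2 fell and Npas4 rose, and adjusted over the list alone 8 fell and 2 rose, Fos falling by 0.36 and 0.46 and Egr1 rising by 0.52 and 0.33. The medians were -0.38 in non-HPX (percentile 0.0) and -0.31 in HPX (percentile 0.01). Of 13 expressed cholesterol synthesis genes, 9 had higher values at night in non-HPX (median 0.15, percentile 99.98) and 12 in HPX (median 0.19, percentile 97.97, but 97.34 after cyclic loess and 96.62 under the stricter filter); adjusted over the list alone, the squalene epoxidase gene Sqle rose by 0.45 and 0.59. Among 9 heat shock genes and chaperones, Dnajb1 rose over all genes, and Hspa1a and Hspa5 rose as well when adjusted over the list alone (medians 0.03, percentile 73.66, and 0.10, percentile 73.66; the means lay at percentiles 99.34 and 99.54). Of 8 expressed markers of other hypothalamic neurons, Hdc, which encodes the histamine-forming enzyme, rose by 0.53 and 0.90, and the medians were -0.06 (percentile 32.81) and -0.07 (percentile 11.4, but 1.43 without the filter and 100 under the stricter filter).

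Microglial markers had medians of -0.16 in non-HPX (percentile 2.63) and -0.19 in HPX (percentile 0.28) over 9 expressed genes, with the most abundant, Ctss, at 0.11 and -0.19. Endothelial and mural markers had -0.17 (percentile 1.05, but 2.93 under the stricter filter) and -0.10 (percentile 3.82) over 12. Oligodendrocyte and myelin markers had -0.02 (percentile 54.97) and -0.11 (percentile 0.57, but 2.78 under the stricter filter) over 13, where Opalin fell when adjusted over the list alone. Astrocyte markers had 0.01 (percentile 76.39) and -0.03 (percentile 9.97) over 11. The 4 expressed markers of GABA neurons had -0.24 (percentile 0.65) and 0.08 (percentile 57.82), 16 excitability channels -0.05 (percentile 22.86) and 0.08 (percentile 68.98), and 4 choroid plexus and ependymal markers -0.03 (percentile 46.91; 0.00 after cyclic loess) and -0.02 (percentile 28.32). By limma 0 genes of these lists passed over all genes for time of day, with 3 oligodendrocyte, 2 microglial and 0 other members at an unadjusted p under 0.05.

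State by state, 45 genes were at least 1.5-fold higher and 79 lower at night in non-HPX, and 106 higher and 94 lower in HPX. In HPX the higher genes made 53.0% of these as deposited and 39.4% after cyclic loess. Without the expression filter the totals were 805 and 834 in place of 124 and 200, and the balance turned in both states. The higher genes then made 60.5% in non-HPX and 43.6% in HPX, in place of 36.3% and 53.0%. Over the 22 genes higher at night in both states the median change was 0.85 in non-HPX and 0.86 in HPX, 11 being larger in each state. Over the 34 lower genes it was -0.83 and -0.89, 22 being larger in non-HPX and 12 in HPX; after cyclic loess 20 of 37 were larger in non-HPX and 17 in HPX. Whether the states differed in these counts or sizes was not tested, since no group has replicates.

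HPX was compared with non-HPX at each time. Oxt (probeset 17376372), which encodes the neurohypophysial hormone oxytocin, differed most: 10.80 in non-HPX against 8.37 in HPX at ZT2 and 10.75 against 9.28 at ZT14, 5.39-fold and 2.77-fold lower. Scrg1 was 2.31-fold and 2.54-fold lower, the extracellular matrix protein Fbln5 2.72-fold and 2.02-fold, Itih3 2.34-fold and 2.33-fold, and the retinaldehyde dehydrogenase Aldh1a1 1.92-fold and 2.56-fold. Th, the rate-limiting enzyme of catecholamine synthesis, was 1.96-fold and 2.05-fold lower. Cyp4f15, Gdf10, Etnppl and the secreted Wnt antagonist Sfrp5 completed the 10, with mean log2 changes from -0.97 to -0.86. The HPX values of Cyp4f15, Gdf10 and Sfrp5 lay below the floor at both times, so the size of these changes is uncertain. No gene outside predicted and non-coding names was at least 1.5-fold higher in HPX at both times; the 1 that was, Gm7361, has a predicted name and was singled out after its values were seen.

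In the additive limma fit 15 genes fell and 0 rose in HPX (519 had an unadjusted p under 0.05), Oxt at -1.95 ± 0.19 (SE; adjusted p = 0.00554), Scrg1 at -1.27 ± 0.11 (adjusted p = 0.00445), Itih3 at -1.23 ± 0.11 (adjusted p = 0.00445) and Aldh1a1 at -1.15 ± 0.13 (adjusted p = 0.0101) among them. The rest included the peptide gene Sst, the transcription factor Klf9, the lipid transporter Mfsd2a and the small nucleolar RNAs Snord66 and Snord1b, of which the last 3 were chosen after their values were seen. Genes named by the rule had been picked for a large mean change shared by both times, so their passing is no separate test. The count was 0 without the expression filter, with 1169 genes at an unadjusted p under 0.05, and 72 after cyclic loess, 17 of them higher. By size alone 25 genes were at least 1.5-fold higher and 69 lower at ZT2, and 17 higher and 52 lower at ZT14. At ZT2 the higher genes made 26.6% as deposited, 39.3% after cyclic loess and 64.8% without the expression filter. At ZT14 they made 24.6% as deposited and 47.5% without the filter. Moving the same way at both times were 1 higher and 16 lower genes, against 0.04 and 0.32 for independent lists. Across all expressed genes the effects at the 2 times had a Pearson's r of 0.007 and a Spearman's rho of -0.105 (-0.178 under the stricter expression filter).

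**Figure D2:**
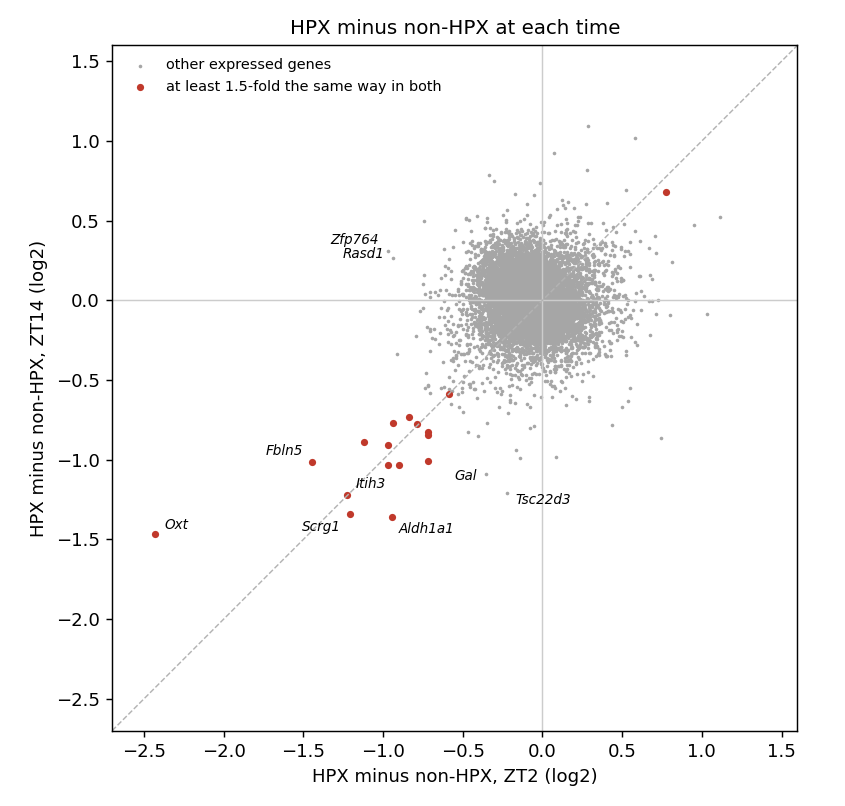
Each point is an expressed gene, with its HPX minus non-HPX difference (log2) at ZT2 on the horizontal axis and at ZT14 on the vertical axis; the dashed line marks equal change and there is 1 array per group. The 17 genes at least 1.5-fold apart the same way at both times are red, 16 of them lower in HPX, and Oxt (-2.43 and -1.47) lies farthest out, while Tsc22d3 (-0.23 and -1.21) differed mainly at ZT14.

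Genes known to respond to glucocorticoids had lower values in HPX at both times. The median over 15 expressed members was -0.19 at ZT2 (percentile 1.02, but 7.56 under the stricter filter; 14 lower) and -0.41 at ZT14 (percentile 0.0; 12 lower), and 1 member at ZT2 against 5 at ZT14 were at least 1.5-fold lower. At ZT14 these were Tsc22d3 (-1.21), the transcription factor Zbtb16 (-0.99), the sulfotransferase Sult1a1 (-0.94), Klf9 (-0.85) and the metallothionein Mt2 (-0.64). Over all genes only Klf9 fell, by 0.72 and 0.85 (adjusted p = 0.0363); adjusted over the list alone Tsc22d3, Sgk1, Zbtb16, Mt2, Sult1a1 and Klf9 fell. At night the list's median was 0.11 above day in non-HPX (percentile 99.67, but 83.02 under the stricter filter) and 0.03 in HPX (percentile 54.13; -0.01 after cyclic loess, where Fkbp5 crossed the floor and joined the list). Dusp1, a member also held by the immediate early list, was the only member to pass over all genes for time of day, and it fell at night; adjusted over the list alone Sgk1 rose.

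**Figure D3:**
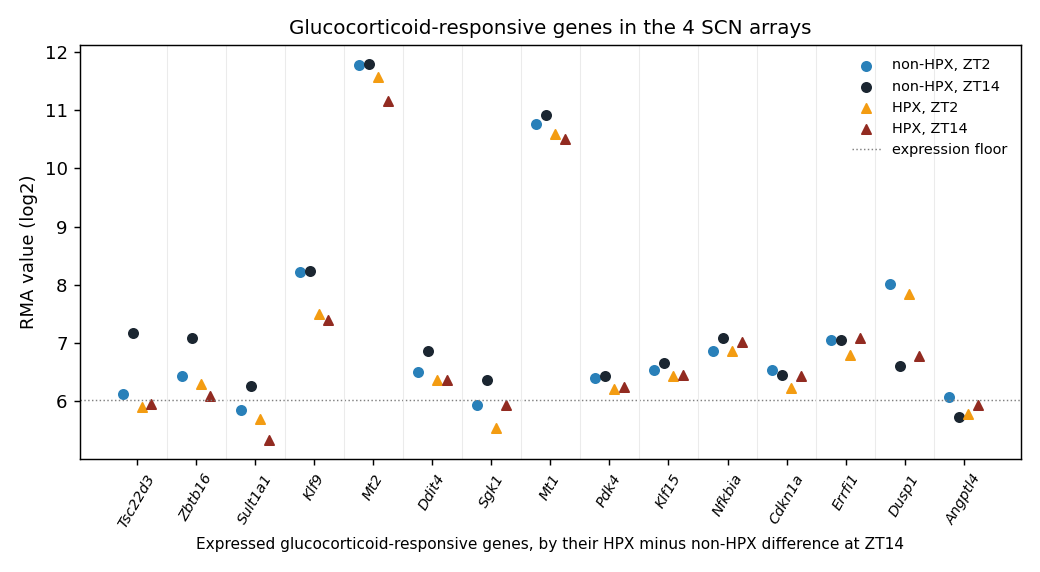
Log2 RMA value of the 15 expressed glucocorticoid-responsive genes in each of the 4 arrays, 1 point per array, ordered by the HPX minus non-HPX difference at ZT14; the dotted line is the expression floor. Tsc22d3 stands at 7.17 in non-HPX at ZT14 and between 5.90 and 6.13 in the other 3 arrays.

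Thyroid hormone-responsive genes had medians of -0.36 at ZT2 (percentile 0.01) and -0.24 at ZT14 (percentile 0.23) over 7 expressed members, 6 of them lower at each time. Aldh1a1 and Klf9 fell over all genes, and Hr fell as well when adjusted over the list alone; Klf9 is shared with the glucocorticoid list. Their night medians were -0.04 (percentile 54.5; 0.00 after cyclic loess) and -0.10 (percentile 12.98). Cholesterol synthesis genes had medians of -0.20 at both times (percentiles 0.34 and 0.0), 13 of 13 lower at ZT2 and 12 at ZT14, with Sqle at -0.19 and -0.06, but 0 passed in the limma fit, over all genes or adjusted over the list alone, where 7 had an unadjusted p under 0.05. Markers of other hypothalamic neurons had medians of -0.32 (percentile 0.05, but 16.78 without the filter) and -0.25 (percentile 0.02), 7 of 8 lower at each time. Oxt and Th fell over all genes and Trh, at -0.38 and -0.52, when adjusted over the list alone. Among the SCN peptides Sst fell by 0.79 and 0.78 (adjusted p = 0.0363). Adjusted over the list alone Gal, Prokr2 and Cartpt fell and Grpr and Penk rose, Gal standing at -0.35 and -1.09 and Penk at 0.12 and 0.63. The peptide list's medians were -0.01 at ZT2 (percentile 87.46; 0.05 after cyclic loess) and -0.06 at ZT14 (percentile 4.57).

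Transcripts of the pituitary hormones themselves (Gh, Prl, Pomc, Cga, Tshb, Lhb and Fshb) were all below the floor in the 4 arrays, so none of the 7 served to check the surgery in this tissue. Growth hormone and IGF signalling genes had medians of -0.22 at ZT2 (percentile 4.61) and 0.29 at ZT14 (percentile 99.92, but 84.59 without the filter) over 5 expressed members, and their night medians were 0.00 (percentile 68.48) and 0.31 (percentile 98.61, but 47.6 without the filter and 91.76 under the stricter filter), with Igfbp5 at 0.11 and 0.59. Those 5 members were Igf1r, Ghsr, Igfbp5, Stat5b and Bcl6. The growth hormone receptor gene Ghr, Igf1, Cish, Socs1, Socs2 and Socs3 were among the members below the floor. The medians therefore do not read out growth hormone signalling as a whole. Receptors for pituitary and target-gland hormones, 5 expressed, had -0.09 (percentile 34.71) and 0.11 (percentile 84.32) for surgery and -0.11 (percentile 17.76) and 0.13 (percentile 79.83) for night. Interferon response genes, 4 expressed, had 0.35 at ZT2 (percentile 99.97) and 0.14 at ZT14 (percentile 90.19) and night medians of -0.08 (percentile 33.14) and -0.50 (percentile 0.05). Adjusted over the list alone, 2 members fell at night, and Ifit1 rose in HPX, standing 0.81 and 0.24 above non-HPX. Only the HPX value of Ifit1 at ZT2 (6.53) reached the floor, so these differences rest on values under it. The stricter filter left 1 of the 4 interferon members. Immediate early genes had -0.17 (percentile 3.76) and 0.12 (percentile 97.28), and SCN identity genes -0.12 (percentile 12.22) and 0.14 (percentile 98.96). Heat shock genes had -0.19 (percentile 1.55, but 2.68 after cyclic loess and 9.3 under the stricter filter) and -0.05 (percentile 10.7), Hspa1a falling when adjusted over the list alone.

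Astrocyte markers stood slightly lower in HPX beside these lists, at -0.12 at ZT2 (percentile 15.18) and -0.11 at ZT14 (percentile 1.07), with the abundant Aldoc at -0.46 and -0.31 and Slc1a3 at -0.12 and -0.04. Oligodendrocyte and myelin markers had -0.02 (percentile 81.63; 0.05 after cyclic loess) and -0.06 (percentile 6.81), with Mobp at -0.20 and -0.60. Microglial markers had -0.01 (percentile 83.78; 0.05 after cyclic loess) and 0.02 (percentile 56.84). Endothelial and mural markers had 0.07 (percentile 98.66, but 69.72 to 96.04 under 5 alternatives, all but the mean with other members) and 0.22 (percentile 99.97); adjusted over the list alone Rgs5 rose and Abcb1a fell. The ZT14 percentile of this list was 31.86 under the stricter expression filter. GABA neuron markers had -0.18 (percentile 11.48) and 0.19 (percentile 98.04, but 97.13 under the stricter filter and 97.19 for the mean), with the most abundant, Gad2, at -0.21 and 0.21. Excitability channels had -0.14 (percentile 4.05) and -0.00 (percentile 33.19), and choroid plexus and ependymal markers -0.15 (percentile 14.55) and -0.10 (percentile 9.76). Of 9 meningeal fibroblast markers 2 were expressed, with HPX minus non-HPX medians of 0.06 and -0.38; of these Dcn fell at night when adjusted over the list alone. The cold-inducible Cirbp, the only measured member of its list, was stood 0.32 and 0.24 higher in HPX and did not pass over all genes (adjusted p = 0.976); adjusted over the list alone, which with 1 member leaves p as it was, p was 0.0314. The 7 red blood cell genes had no probeset of their own. The 3 expressed members of the sex-linked list had night medians of 0.16 (percentile 97.67, but 97.4 under the stricter filter) and -0.09 (percentile 10.07) and surgery medians of 0.10 (percentile 95.56) and -0.14 (percentile 4.66).

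The night change was then compared between HPX and non-HPX. At least 2-fold apart were 5 genes in which the change in HPX was the more positive and 7 in which it was the more negative; without the expression filter the total was 300 in place of 12. Rasd1 rose by 2.15 in non-HPX and 3.35 in HPX, a difference of 1.20. Tgfb1i1 differed between night and day by 0.28 in non-HPX and 1.33 in HPX. Zfp764 (1.28), Ccdc65 (0.99) and Reep4 (0.96) had the most positive differences besides, predicted and non-coding names aside. At the other end stood Klhl21 (-1.17), Ctla2a (-1.10), Tsc22d3 (-0.99), Crip1 (-0.89) and Serpinb1b (-0.87). Tsc22d3, the glucocorticoid-induced leucine zipper, was 1.04 above its day value at night in non-HPX and 0.06 in HPX. Rasd1 reached 10.59 in HPX at night, Tgfb1i1 7.42 in HPX at night and Tsc22d3 7.17 in non-HPX at night, but both HPX values of Tsc22d3 lay below the floor of 6.02. The others reached no more than 1 log2 unit above the floor. Among them Klhl21, Ctla2a, Serpinb1b, Zfp764 and Reep4 lay below it in some arrays, so their differences rest partly on values under the floor. A saturated design leaves no residual, so none of these differences has an error.

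By list, the difference of differences had medians of -0.09 for glucocorticoid-responsive genes (percentile 3.38, but 0.03 to 1.68 under 6 alternatives, 5 of which change the members), 0.33 for immediate early genes (percentile 99.78), 0.26 for SCN identity genes (percentile 98.79), 0.37 for GABA neurons (percentile 98.27), 0.48 for growth hormone and IGF signalling (percentile 99.89, but 97.06 without the filter), -0.35 for interferon response (percentile 0.65), -0.14 for oligodendrocytes and myelin (percentile 0.18) and -0.23 for sex-linked transcripts (percentile 1.62). The other lists lay within the bounds. The core clock had 0.16 (percentile 88.96) and no clock gene reached a 2-fold difference. Its values were positive for 15 genes, among them Nr1d1 (0.61) and Cry2 (0.50), and negative for 5. The additive fit for surgery does not measure such differences. The median over all expressed genes was itself 0.07 as deposited and 0.00 after cyclic loess. Of the 100 combinations of a list and a difference, 36 lay in the lowest or highest 2.5% of the random lists, where 5 would by chance if list members were independent.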

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

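All tests of explanations in this part were chosen only after the result was seen. Each named difference below rests on 1 array per group.

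Glucocorticoid-responsive genes were lower in HPX at ZT14, with a median of -0.41 over 15 expressed members. After cyclic loess the median of the same 15 was -0.42, while the lowest of 10000 random lists' medians was -0.21. RMA had left little for cyclic loess to move, the median over all expressed genes being 0.012 at ZT14 as deposited. The result therefore argues only against a remaining offset that follows intensity, and it cannot judge other scaling between arrays. The lowest median minus 1 SD over 4 lists of glia and vessel cells at ZT14 was -0.3, above the glucocorticoid list's -0.41. Such an SD measures how the markers differ, so it cannot decide whether a lower share of these cells in HPX contributed. The medians were -0.11 for astrocytes, -0.06 for oligodendrocytes and myelin, 0.02 for microglia and 0.22 for endothelial and mural cells. Loss of a night rise of these genes in HPX stays open as a hypothesis, since the difference of differences lay at percentile 3.38, while 6 of the 7 alternatives put it below 2.5, 5 of them with other members. A direct effect of the lost adrenal drive may contribute, but hormone levels were not measured. A fall of this size also occurred outside the list. At ZT14 the medians of 22 gene families, chosen after their values were seen, ran from -0.44 (Snord) to 0.16 (Pcdh).

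Oxt was lower in HPX at both times. After cyclic loess its mean difference was -1.93. As RMA had left only small offsets to remove, this argues only against a remaining offset that follows intensity and cannot judge other scaling. Fewer neighbouring hypothalamic cells in the HPX tissue could lower it together with markers of such cells. The median over the 7 other expressed markers of other hypothalamic neurons was -0.22, and 5 of the 7 were lower at both times. That median lay between bounds for such a loss and for its absence. Both bounds were set after the result was seen. Whether the 7 markers come from cells near the oxytocin neurons was not measured, so the median cannot decide. Dissection and an effect of surgery on oxytocin neurons, which project to the posterior pituitary, cannot be told apart with 1 pool per group. The effect on these neurons was not tested.

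The 15 genes that fell in HPX had a median mean difference of -0.97. After cyclic loess their mean differences had a median of -0.96 and reached no higher than -0.74. Here too this argues only against an offset that follows intensity and was left after RMA, and it cannot judge other scaling between arrays. The astrocyte list had a median minus 1 SD of -0.25, while the 15 genes reached no higher than -0.77. This cannot decide whether a lower share of astrocytes in HPX contributed. The 15 were selected for low values in HPX on these same arrays, and an SD across markers does not bound a change in share. Loss of glucocorticoid and thyroid hormone drive stays open: 2 of the 15, Klf9 and Aldh1a1, belong to those lists, against 0.03 by chance, and the other 13 are in neither. What lowered the others was not tested, and causes other than surgery stay open. Snord66 and Snord1b belong to a family lower in HPX as a whole (median -0.44 at each time over 37 members), which RNA preparation or the single pool could also give.

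Several genes had night changes of opposite sign in the 2 surgical states, and for each the difference was not tested. The change in HPX minus that in non-HPX was -1.17 for Klhl21 (0.39 in non-HPX and -0.78 in HPX), -1.10 for Ctla2a, -0.89 for Crip1, -0.87 for Serpinb1b, 1.28 for Zfp764, 0.99 for Ccdc65 and 0.96 for Reep4. Opposite signs were common, at 48.2% of expressed genes for the night changes and 56.1% for the surgery effects. Gm12238, a predicted gene, stood 0.74 higher in HPX at ZT2 and at -0.87 at ZT14, a difference of -1.61 that was not tested. All 4 GABA neuron markers were lower in HPX at ZT2 and higher at ZT14, with a median difference of 0.37 that was not tested. Of these, Slc32a1 averages probesets that disagreed, at -0.40 and 0.16 for the first and 0.07 and -0.11 for the second. All 3 sex-linked members stood higher at night in non-HPX and lower in HPX, and higher in HPX at ZT2 and lower at ZT14, with a median difference of -0.23, which is 1 and the same value for both pairs by construction; the difference was not tested.

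Probesets outside the gene-level comparisons also carried differences of at least 1.5-fold. Of 815 probesets above the floor that name several genes, 4 moved the same way at night in both states (0.09 for independent lists) and 2 in HPX at both times (0.21 for independent lists). Of 5508 unnamed probesets above the floor, 108 moved the same way at night in both states (39.95 for independent lists) and 58 in HPX at both times (22.78 for independent lists).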

How the results depend on the processing

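Every alternative reported in this part was planned. With 1 array per group leaving out an array would leave the additive fit 0 residual degrees of freedom, and no paired analysis was possible because the labels pair no samples. Genes near background limit the counts, as the changes below with the expression filter show.

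Without a filter on expression, genes at least 1.5-fold apart numbered 805 for night in non-HPX, 834 for night in HPX, 126 shared by both states, 751 for surgery at ZT2, 592 at ZT14, 59 shared by both times and 300 for the difference of differences, as more genes near background were counted; the additive fit called 1 gene for time of day and 0 for surgery. With the stricter filter these counts were 54, 105, 33, 44, 28, 11 and 2, as fewer genes were counted. At 2-fold (3-fold for the difference of differences) they were 24, 24, 8, 7, 12, 4 and 1, as the threshold itself was higher. After cyclic loess the additive fit called 244 genes for time of day and 72 for surgery, with 52.84 prior degrees of freedom in place of 8.772; the cause was not tested beyond that. These totals stayed within 1.5 times under centring, the other probeset choice, an intensity trend and robust fitting. Lists in the outer percentiles numbered 26 under the stricter filter, where fewer lists had enough members, 45 with list means in place of medians, and 35 to 37 under the other settings.

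Among list percentiles, the SCN neuropeptides and their receptors turned to 0.24 for night in non-HPX and 0.65 in HPX with the mean in place of the median, as Prok2 dominates the mean. Growth hormone and IGF signalling for night in HPX turned to 47.6 without a filter, other hypothalamic neurons for night in HPX to 100 with the stricter filter, and endothelial and mural cells at ZT14 to 31.86 with the stricter filter, as the members counted changed. Besides those given with their results, lists that entered the outer percentiles included, with the mean, SCN identity for night in HPX (99.79), immediate early genes at ZT2 (1.3), oligodendrocytes and myelin at ZT14 (1.74) and sex-linked transcripts for night in HPX (2.31) and at ZT2 (99.83). Without a filter they included excitability channels (1.48), immediate early genes (1.18) and sex-linked transcripts (99.4) at ZT2, and neuropeptides for the difference of differences (99.18). With the stricter filter they included neuropeptides at ZT2 (99.68) and for the difference of differences (97.95), the core clock for the difference of differences (97.72) and oligodendrocytes and myelin at ZT14 (0.11). With 10 expression bins microglia for night in non-HPX lay at 2.18. The cause of these shifts was not tested. Members near the floor changed some lists even without a change of filter: Fkbp5 joined the glucocorticoid list under centring and cyclic loess, and Tagln left the endothelial and mural list under centring and the other probeset choice. For single genes, the probeset with the highest mean moved the night change in non-HPX of Tef to -0.07 and of Slc32a1 to -0.37.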

Other observations

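The genes and families in this part, and the family test, were chosen only after the values were seen.

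Further genes passed the additive fit for time of day outside the naming rule. Lower at night in both states were the endoplasmic reticulum stress factor Creb3l1 (-1.33 in non-HPX and -0.77 in HPX), the calcineurin regulator Rcan1 (-0.84 and -0.80), the small GTPase Gem (-0.68 and -1.08), the phosphatase Ptp4a1 (-0.75 and -1.10) and the microRNA gene Mir212 (-0.65 and -1.17). Higher at night were the matricellular protein Ccn3 (0.90 and 0.86), the adaptor Grb14 (0.84 and 0.83), the potassium channel Kcnh8 (0.70 and 0.66) and the kinase Map3k5 (0.68 and 0.79).

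Small nucleolar RNAs of the Snord family stood lower in HPX at both times. The median over 37 expressed members was -0.44 at ZT2 (31 lower) and -0.44 at ZT14 (36 lower), each at percentile 0.0, and it was -0.39 and -0.45 after cyclic loess. The 46 expressed ribosomal protein genes had a night median of -0.02 in non-HPX and -0.23 in HPX (41 lower; -0.27 after cyclic loess), and HPX minus non-HPX medians of 0.12 at ZT2 and -0.06 at ZT14. Across the 22 families examined, 45 of 110 medians lay in the outer percentiles as deposited and 41 after cyclic loess. Such a percentile was thus common among these families, and the reason was not tested. Single genes stood apart too, though none of the following passed the additive fit for surgery. The complement gene C4b was 0.58 and 1.02 higher in HPX and the cystine transporter Slc7a11 0.29 and 1.09. Of these, Slc7a11 reached the floor only in HPX at ZT14 (6.11), so its differences are uncertain. The non-HPX values of C4b (6.10 and 6.07) lay just above the floor. The prostaglandin D synthase Ptgds stood at -0.47 and -0.82 and the potassium channel Kcnj10 at -0.71 and -0.58.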
